A study of Mus musculus with 12 samples.

How the data were processed

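Total RNA of mouse CD4+ T cells was measured on 12 single-colour microarrays in 4 groups of 3: naive cells from the spleen of B6.2d2 mice, Th17 cells differentiated in vitro, transferred Th17 cells taken from the CNS of Rag1-deficient recipients, and CD4+ T cells from the CNS of C57BL/6 mice immunised with a MOG peptide. Replicates came from 3 independent experiments, per the series text. Per the labels' protocols, RNA was extracted with NucleoSpin RNA II, and 100 ng of each sample was amplified and labelled with Cy3 using the LIQA kit. Neither the purity nor the sort of the isolated cells is given in the labels.

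The intensity values of each spot (processed signal, mean signal and local background) were made with Agilent Feature Extraction 10.7.3.1 and protocol GE1_107_Sep09, per the file headers, with background subtraction and detrending within each array and no normalization between arrays. The use of Agilent Feature Extraction is also given by the submitters' processing notes. The deposited series matrix holds a second set of intensity values, and its normalization is not stated. It has 39429 probes and 149 empty cells, and its median per array of 50.4 to 51.2 and 75th percentile of 801 to 808 were almost alike, as after normalization between arrays. Each array correlated across probes at 0.998 or more with its own column and at most 0.991 with another. The matrix was used only as an alternative. Probe coordinates are those of the file headers' mm9 assembly.

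Of 44397 spots per array, 43020 were not controls. Between 120 and 180 spots per array that the software marked as outliers were left out, and 0 were saturated. Repeated spots were averaged (399 probes with 10 spots each), and 24 of 39429 probes were left out because their single spot was marked on an array, so 39405 were used. Genes were named by RefSeq accession for 27234 probes, by a current symbol for 3576 and by an updated synonym for 565, and 8054 probes kept the name in the file, in all 30101 names. Values were log2 processed signals minus the array's 75th percentile over non-control probes (a signal of 686 to 1023). Median signals were 41.5 to 65.8 and negative controls 24.3 to 32.6. Signals well above background reached down to log2 levels of −5.95 to −5.17, and where a group had an array below that level, a called fold change is given as a lower bound with its values raised to that level. A gene was represented by its probe with the highest mean, and kept if well above background on all 3 arrays of at least 1 group, which left 18630 genes.

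All 12 arrays entered 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), with 8 residual and 2.485 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, called under 0.05, and a 2-fold count uses a log2 change of 1. Adjusted p-values of genes are two-sided and come from this limma model. SE is that of the fit and SD that of 3 arrays. The 6 pairs of groups were compared, and a 7th result counts genes called in the same direction for both CNS groups against both others. Scripts also used the data.table package (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

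The groups, comparisons, tests, alternatives, named-gene rule and 26 gene lists were chosen before the data were examined. The lists covered T helper, regulatory, naive and co-inhibitory programmes, cell cycle, metabolism, hypoxia, interferon, adhesion, activation, cytokine and heat shock genes, a T cell core, and markers of 9 other cell types. They overlap, with 28 genes in several lists. For each list the members called over all genes and adjusted over the list alone were counted, and limma camera was run with a preset inter-gene correlation of 0.01, adjusted over all 156 tests of lists and comparisons. Camera with an estimated correlation and fry were alternatives. With an estimated correlation no list was called, and the lowest adjusted p was 0.159. Named genes were, among called genes whose groups did not overlap, the 7 largest rises and falls measured on all 6 arrays, the 4 largest bounds from or to background, up to 4 called members per list, and 18 T cell genes fixed in advance. For the last 3 comparisons 3 genes each way were named. Some genes that this rule would name are not reported here.

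Replicate number also marks the slide, and each of 3 slides held 4 arrays, 1 per group, at a position fixed by group. Slide was therefore fitted as a block, which leaves fold changes unchanged in this balanced design, and list medians were also taken within slides. Other alternatives were 5 normalizations, other filters on dim probes, other ways to choose a probe, array weights, a trended robust prior, only the 6 arrays compared, stricter thresholds and leaving out each array in turn. Simulated groups without change gave the correlation that shared controls produce when no gene changes.

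The fit was tested on simulated data with 200 of 18630 genes changed, 100 each by 1 and 2 log2 units. It recovered 24% and 72% for Th17 against naive cells, 29% and 79% for transferred against cultured cells, and 20% and 73% between CNS groups, where 3.03%, 6.9% and 3.12% of calls were false. In the other comparisons it recovered 31% and 75%, 27% and 80%, and 22% and 86%, with 5.36%, 4.46% and 3.57% false calls. Changes of 2-fold were thus mostly missed in this simulation. Each real comparison called more than 200 genes, and the Benjamini-Hochberg cutoff loosens as more genes change. These recoveries therefore do not carry over to the real comparisons. Of 49 unshifted lists 0 to 3 had a p under 0.05 in each comparison.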

Results

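The data were gene expression profiles of mouse CD4+ T cells from experimental autoimmune encephalomyelitis (EAE), a model of multiple sclerosis. A 1-colour microarray was hybridised with each of 12 RNA samples in 4 groups of 3. The first group held naive CD4+ T cells from the spleen of B6.2d2 mice, whose transgenic T cell receptor recognises myelin oligodendrocyte glycoprotein (MOG). The second held Th17 cells differentiated from such cells in culture. For the third, cultured Th17 cells were transferred into mice that lack Rag1 and so have no mature T or B cells of their own, and CD4+ T cells were taken back from the central nervous system (CNS) at the peak of disease. The fourth held CD4+ T cells from the CNS of C57BL/6 mice immunised with a MOG peptide, called the immunised group here. Between 57% and 64.8% of the non-control probes were well above background on each array. The precision of every value was limited by 3 arrays per group.

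Levels are log2 signals relative to the 75th percentile of the same array, and 18630 genes were tested. Across genes, arrays of 1 group correlated at 0.976 to 0.982 for naive cells, 0.954 to 0.985 for cultured Th17 cells, 0.976 to 0.984 for transferred cells and 0.982 to 0.991 for the immunised group. The first principal component held 54.0% of the variance and the second 23.5%. Cultured Th17 cells were the most variable group, with a median SD per gene of 0.35 against 0.206 in the immunised group. Their replicate 3 stood apart for Ifng, the gene of interferon gamma, at −4.22 against 1.42 and 4.26 on the other arrays of that group.

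The first comparison asked how naive cells changed on differentiation into Th17 cells. Il17a and Il17f, the cytokine genes that define Th17 cells, were 10.10 ± 0.80 and 9.43 ± 0.79 log2 higher in culture (SE of the limma fit, 3 arrays per group). Il17a had a mean level of 4.47 ± 1.78 in culture (SD, n = 3) and −5.63 ± 0.68 in naive cells (SD, n = 3), where it was well above background on 1 of 3 arrays, so the rise was at least 984-fold. Il23r, a subunit of the interleukin-23 receptor, was 5.62 ± 1.18 higher. The lymph node chemokine receptor gene Ccr7 changed by −2.54 ± 0.41. In mm9 coordinates from the array files, the Il17a probe lies on chromosome 1 from 20724404 to 20724463. Whether a probe lies in a coding exon or a UTR was not analysed here.

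Of 15 measured members of the Th17 programme list, 14 rose (14 adjusted over the list alone) with a list median of 4.25, and 3.63 to 4.95 within the 3 slides. The camera adjusted p was 1.78e-08, against an adjusted p = 0.19 with an estimated correlation. Il21, a cytokine gene, rose by 7.44 and Il1r1, an interleukin-1 receptor gene, by 6.15, while Ccr6 differed by −1.09 ± 1.34 (adjusted p = 0.546). In the pathogenic Th17 set 9 of 14 genes rose and 0 fell (10 adjusted over the list alone), with a median of 3.65, or 3.08 with genes at background set to their bound, and 2.0 to 4.09 within slides. Its camera adjusted p was 0.000175 and the adjusted p = 0.318 with an estimated correlation. Csf2, the gene of the growth factor GM-CSF, was not well above background in naive cells and was at least 8.49-fold higher in culture, the chemokine gene Cxcl3 at least 45.5-fold, and the galectin gene Lgals3 rose by 5.63. The secreted cytokine list had 8 genes higher and 1 lower of 19 (11 adjusted over the list alone; median 2.56, or 2.08 at the bounds, and 1.78 to 2.13 within slides), at adjusted p = 0.00121 with camera and adjusted p = 0.282 with an estimated correlation. Ifng differed by 0.37 ± 1.60 (adjusted p = 0.874; 0.0228 to 1 over all alternatives), by −1.515 without culture replicate 2 and by 2.725 without replicate 3 (adjusted p = 0.386 and 0.0228). Tbx21, which encodes the Th1 factor T-bet, differed by 1.62 ± 0.64 (adjusted p = 0.0675; 0.000112 to 0.257 over all alternatives). It was called without culture replicate 3, at 2.57.

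In the naive and quiescence list 13 of 16 genes fell and 1 rose (14 adjusted over the list alone; median −2.26, and −2.41 to −1.92 within slides), and 9 were called without naive replicate 3. Its adjusted p was 2.71e-05 with camera, with an adjusted p = 0.386 with an estimated correlation. Dapl1 fell at least 1120-fold (well above background on 1 of 3 cultured arrays), the gut homing receptor Ccr9 by 7.61 and Klf2, a quiescence factor, by 5.21. Among 14 regulatory T cell genes 10 rose and 3 fell (13 adjusted over the list alone; median 3.09, and 1.71 to 4.26 within slides; adjusted p = 0.00231 with camera and adjusted p = 0.206 with an estimated correlation). Ctla4, an inhibitory receptor gene, rose by 6.36 and Il2ra, the high-affinity interleukin-2 receptor chain, by 5.63, while Ikzf2 fell at least 42.6-fold and Foxp3, the lineage factor of regulatory T cells, by 2.24 ± 0.51. Co-inhibitory receptor genes followed with 8 higher and 3 lower of 12 (11 adjusted over the list alone; median 2.20, and 1.83 to 3.19 within slides; adjusted p = 0.00825 with camera and adjusted p = 0.22 with an estimated correlation), among them Havcr2, at least 65.3-fold higher, and Tox, at least 40.2-fold lower. The Th1 list had 7 higher and 1 lower of 16 (8 adjusted over the list alone), with Cxcr6 at 5.44 and Gzmb, a cytotoxic granule protease gene, at 4.34. Its median was 0.87, within slides −0.11 on slide 3, and 2.14 without culture replicate 3 (adjusted p = 0.0175 with camera and adjusted p = 0.415 with an estimated correlation). Chemokine receptor and adhesion genes moved both ways, with 11 higher and 6 lower of 25 (17 adjusted over the list alone; camera adjusted p = 0.138) such as the monocyte and T cell chemokine receptor gene Ccr2 at 5.93. Of 6 Th2 genes 2 rose, and 4 without culture replicate 2 (camera adjusted p = 0.101), with Ccr4 at 3.63 and Ccr8 at least 10.3-fold higher.

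Growth and metabolic genes rose together. Of 23 cholesterol synthesis genes 22 rose (23 adjusted over the list alone; median 1.96, and 1.39 to 2.22 within slides), at adjusted p = 4.6e-11 with camera and adjusted p = 0.22 with an estimated correlation, for example Hsd17b7 at 3.86, Fdps at 2.50 and Sqle at 2.39. Of 18 glycolysis genes 16 rose (16 adjusted over the list alone; median 2.64, and 1.87 to 3.43 within slides), at adjusted p = 3.44e-10 with camera and adjusted p = 0.256 with an estimated correlation. Hk2, the hexokinase that phosphorylates glucose, rose at least 174-fold and the lactate exporter gene Slc16a3 by 7.10. The cell cycle list had 20 of 25 genes higher (20 adjusted over the list alone; median 2.46, and 1.81 to 3.63 within slides; adjusted p = 2.01e-09 with camera and adjusted p = 0.325 with an estimated correlation). Mki67, a proliferation marker, rose by 2.92 ± 0.39, the topoisomerase gene Top2a by 3.44 and the mitotic kinase gene Bub1 at least 11.8-fold. Hypoxia response genes numbered 6 higher and 1 lower of 9 (7 adjusted over the list alone; median 4.29, and 2.65 to 6.60 within slides; adjusted p = 0.00231 with camera and adjusted p = 0.474 with an estimated correlation), with the angiogenic factor gene Vegfa at least 63.9-fold higher and Bnip3 at 5.23. Interferon-stimulated genes went the other way, with 13 of 24 lower and 0 higher (13 adjusted over the list alone; median −1.89, and −2.31 to −0.78 within slides; adjusted p = 0.00159 with camera and adjusted p = 0.593 with an estimated correlation). Oas2 fell by 5.84 and Oasl1 by 5.66.

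By the fixed ranking, the largest rises among genes measured on all 6 arrays included Lilr4b at 8.51, the leukotriene receptor gene Ltb4r1 at 8.11, Lilrb4a at 8.03 and Upp1 at 7.97. The largest falls were Dtx1, a Notch pathway gene, at −8.56, Ccr9, Ms4a4b at −6.87, Pdlim4 at −6.46 and Klf3 at −6.29. From background, Stc2 rose at least 187-fold and Foxf1 at least 176-fold, and to background Chil5 fell at least 88.9-fold and Klrg1 at least 33.6-fold. Markers of other cell types also differed. Macrophage and monocyte genes had 9 higher and 2 lower of 18 (12 adjusted over the list alone; median 1.12, and 0.73 to 1.87 within slides; adjusted p = 0.0231 with camera and adjusted p = 0.561 with an estimated correlation), with Cd14 at least 23.0-fold higher. Of 6 CD8 and NK cell genes 3 fell (3 adjusted over the list alone; adjusted p = 0.0457 with camera and adjusted p = 0.409 with an estimated correlation), with Cd8b1 at −2.62.

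In total 7463 genes passed the limma test, 3672 higher and 3791 lower in culture, and 2697 and 2278 of these changed at least 2-fold. That balance depended on scaling, with 3507 higher and 2757 lower under median scaling. With slide as a block 7167 genes were called. Each slide carried 1 array per group at a fixed position, so array position and group cannot be told apart.

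**Figure D1:**
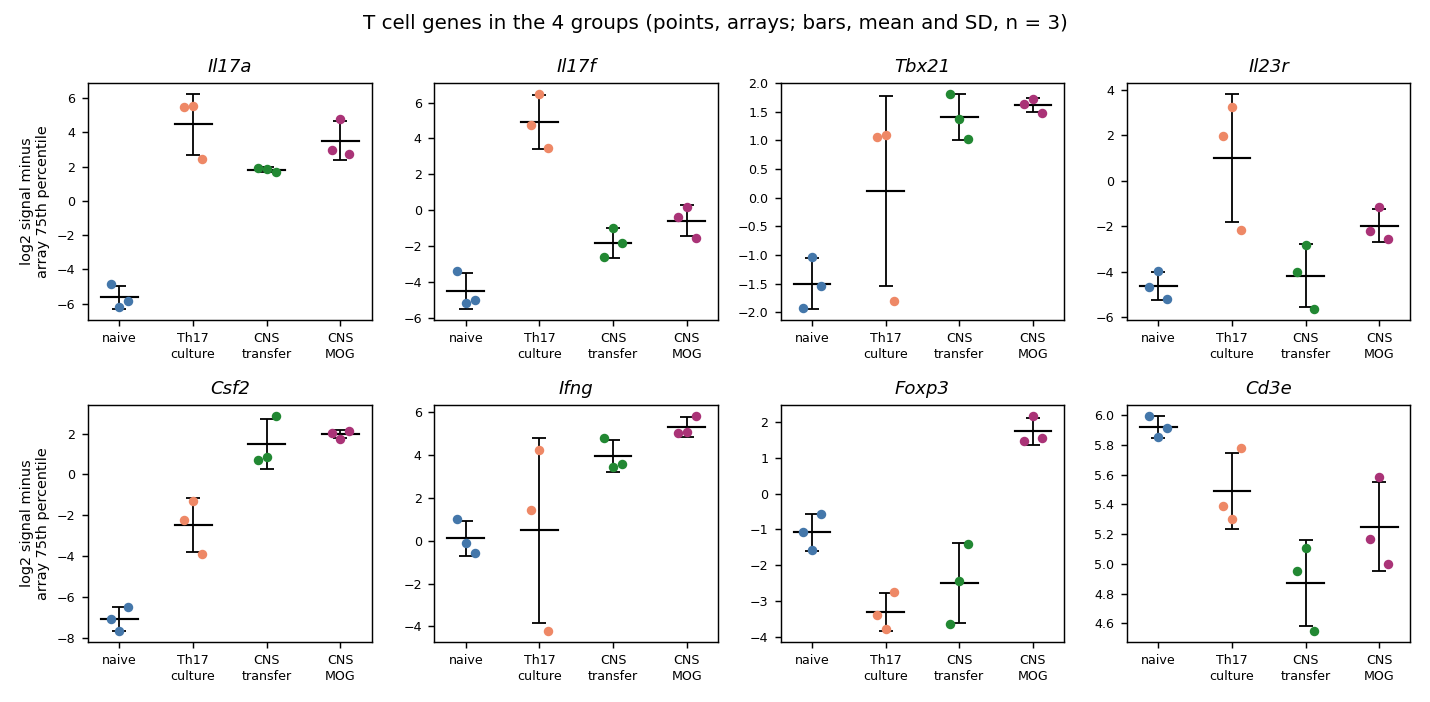
Level of 8 T cell genes on each of the 12 arrays, as log2 signal minus the array's 75th percentile on the vertical axes, by group on the horizontal axes, with bars for mean and SD (n = 3). Group means of Il17a, Il17f and Il23r were highest in cultured Th17 cells, Csf2 was higher in both CNS groups than in the others, and Foxp3 was highest in the immunised group at 1.75 ± 0.38.

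The second comparison asked how cultured Th17 cells changed after transfer and re-isolation from the CNS. Genes of macrophages rose most: Apoe, encoding the lipid carrier apolipoprotein E, was 10.28 ± 0.31 log2 higher (limma SE), at 8.25 ± 0.22 in transferred cells (SD, n = 3) against −2.03 ± 0.46 in culture (SD, n = 3). The complement genes C1qa and C1qc, not well above background in culture, were at least 2009-fold and 3168-fold higher. Il17f fell by 6.74 ± 0.79 (adjusted p = 0.00017) and Il22 by 5.86 ± 1.14. Csf2 rose by 3.97 ± 0.68 (adjusted p = 0.0019). The probes for Apoe and Csf2 lie on mm9 chromosome 7 from 20281732 to 20281791 and on chromosome 11 from 54060772 to 54060799.

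Of 15 Th17 programme genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; median −1.41, and −1.79 to −0.66 within slides), at adjusted p = 0.021 with camera and adjusted p = 0.485 with an estimated correlation. Il17a fell by 2.65 ± 0.80 (adjusted p = 0.031). That call was lost without culture replicate 1 (adjusted p = 0.103) or 2 (0.0998), or without transfer replicate 1 (0.0639), 2 (0.0722) or 3 (0.0844), and over all alternatives the adjusted p ran from 0.000393 to 0.104. Its level in transferred cells was at least 157-fold above naive cells. The pathogenic Th17 set moved both ways, with 6 higher and 3 lower of 14 (10 adjusted over the list alone; median 1.03; camera adjusted p = 0.164), including the chemokine genes Ccl4 at 5.03 and Ccl3 at 4.58. Secreted cytokine genes had 7 higher and 4 lower of 19 (12 adjusted over the list alone; median 2.35, and 0.44 to 2.10 within slides; adjusted p = 0.0191 with camera and adjusted p = 0.409 with an estimated correlation). Its median was 1.19 without culture replicate 2 and 1.40 without culture replicate 3. Il2, the T cell growth factor gene, rose at least 71.5-fold and Il6 by 5.07. Ifng differed by 3.47 ± 1.60 (adjusted p = 0.133), but by 5.36 without culture replicate 2 (adjusted p = 0.0154) and 1.12 without replicate 3 (adjusted p = 0.332), with adjusted p from 0.0154 to 0.332 over all alternatives. Tbx21 differed by 1.28 ± 0.64 (adjusted p = 0.164; 0.0785 to 0.595 over all alternatives), and by 0.33 without culture replicate 3 (adjusted p = 0.431). The Th1 list had 3 genes higher and 5 lower of 16 (4 and 6 adjusted over the list alone), with Fasl, a death ligand gene, at 3.54 and Il12rb2 at −2.56. Its median of −0.55 and its mean of 0.36 differed in sign, and camera gave an adjusted p = 0.877 for a fall.

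Immediate early genes, which T cells and other cells switch on within minutes of stimulation, had 14 of 18 members higher and 0 lower (16 higher and 1 lower adjusted over the list alone; median 3.50, and 2.79 to 3.71 within slides). The adjusted p was 1.59e-08 with camera, with an adjusted p = 0.256 with an estimated correlation, and Fosb rose by 8.04, Fos by 7.42, Atf3 by 5.46 and Dusp1 by 5.27. Interferon-stimulated genes had 10 of 24 higher and 0 lower (10 adjusted over the list alone; median 1.70, and 0.53 to 2.82 within slides), for example Oasl1 at 5.84 and Ifi44 at least 18.3-fold higher. The adjusted p was 0.000128 with camera, with an adjusted p = 0.521 with an estimated correlation, and 6 were called without transfer replicate 2. Cholesterol synthesis genes fell, 21 of 23 (21 adjusted over the list alone; median −1.94, and −2.16 to −1.76 within slides; adjusted p = 6.66e-14 with camera and adjusted p = 0.206 with an estimated correlation), with Hsd17b7 at −3.16, Fdps at −3.13 and Sqle at −2.68. Of 18 glycolysis genes 8 fell (9 adjusted over the list alone; median −0.76, and −1.09 to −0.52 within slides; adjusted p = 0.00133 with camera and adjusted p = 0.533 with an estimated correlation), with the glucose transporter gene Slc2a3 at −3.67 and Aldoc at −3.11. Only 4 were called without culture replicate 3 or transfer replicate 1, and 5 without naive replicate 2, transfer replicate 2 or immunised replicate 1. The cell cycle list had 1 of 25 genes lower (camera adjusted p = 0.296), and 2 without naive replicate 1 or 4 without culture replicate 2. Hypoxia response genes numbered 1 higher and 4 lower of 9 (6 adjusted over the list alone; camera adjusted p = 0.0964), with Adm at −4.18 and Vegfa at 2.74. Of 9 heat shock genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.115), with Hspa1a at least 37.8-fold higher, and 1 was called without culture replicate 1 or transfer replicate 3. Camera called that list without culture replicate 3 (median 0.56 against 0.24; adjusted p = 0.0125).

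Beside each of these changes, markers of other cells rose on the same arrays. Of 18 macrophage and monocyte genes 17 rose (17 adjusted over the list alone; median 5.73, and 5.37 to 6.56 within slides), at adjusted p = 3.29e-19 with camera and adjusted p = 0.159 with an estimated correlation. Of 8 microglia genes 7 rose (7 adjusted over the list alone; median 4.32, or 4.10 at the bounds, and 4.11 to 5.14 within slides), at adjusted p = 8.01e-07 with camera and adjusted p = 0.159 with an estimated correlation. P2ry12, a purine receptor gene of microglia, was at least 37.9-fold higher and Olfml3 rose by 4.47. Neutrophil markers had 6 higher and 1 lower of 10 (7 adjusted over the list alone; median 2.98, and 0.59 to 4.85 within slides; adjusted p = 0.0097 with camera and adjusted p = 0.459 with an estimated correlation), with Retnlg at least 55.8-fold higher. Of 5 dendritic cell genes 3 rose (3 adjusted over the list alone; median 3.52; adjusted p = 0.00923 with camera and adjusted p = 0.215 with an estimated correlation), with the integrin gene Itgax at 3.88. Of 12 neural and glial genes 4 rose (5 higher and 1 lower adjusted over the list alone; median 1.62, or 1.40 at the bounds, −0.18 over members well above background on all 12 arrays, and 0.59 to 2.13 within slides; adjusted p = 0.04 with camera and adjusted p = 0.459 with an estimated correlation), with the glutamate transporter gene Slc1a3 at least 3.80-fold higher. Of 6 CD8 and NK cell genes 2 rose and 1 fell (3 adjusted over the list alone; median 1.22, and 0.58 without transfer replicate 2; camera adjusted p = 0.0829), with the NK receptor genes Klra8 and Klrb1c at least 13-fold and 6.13-fold higher. B cell markers had 1 higher and 4 lower of 7 (6 adjusted over the list alone; camera adjusted p = 0.496). No erythroid gene of 2 passed the limma test, nor an unadjusted p under 0.05. The T cell core list had 4 of 12 genes lower (7 adjusted over the list alone; median −0.65, and −0.77 to −0.53 within slides; adjusted p = 0.00393 with camera and adjusted p = 0.488 with an estimated correlation), and 2 without transfer replicate 3. Cd2 fell by 1.18 and Cd3d by 1.06, and Cd3e, a chain of the T cell receptor complex, differed by −0.62 ± 0.21 (adjusted p = 0.0514).

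Other leading rises were Chil3 at 9.57, C1qb at 8.81, Gdf15 at 8.51 and Arg1, the arginase of alternatively activated macrophages, at 8.13, with the chemokine genes Ccl7 and Ccl12 at least 1190-fold and 320-fold higher. Cx3cr1, the fractalkine receptor gene of microglia and monocytes, rose at least 245-fold in a chemokine receptor and adhesion list with 7 higher and 6 lower of 25 (17 adjusted over the list alone; median 0.35, and 0.77 without transfer replicate 3; camera adjusted p = 0.244). The largest falls included Enpp2 at −7.42, Il17f, Il22 and Prss12 at −5.38, and Gipr fell to background by at least 51.0-fold. The limma test called 5267 genes, 2385 higher and 2882 lower in transferred cells, of which 1929 and 1729 changed at least 2-fold. This balance too depended on scaling, with 2644 higher and 2442 lower when scaled on probes above background on all arrays. With slide as a block 5069 genes were called.

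**Figure D2:**
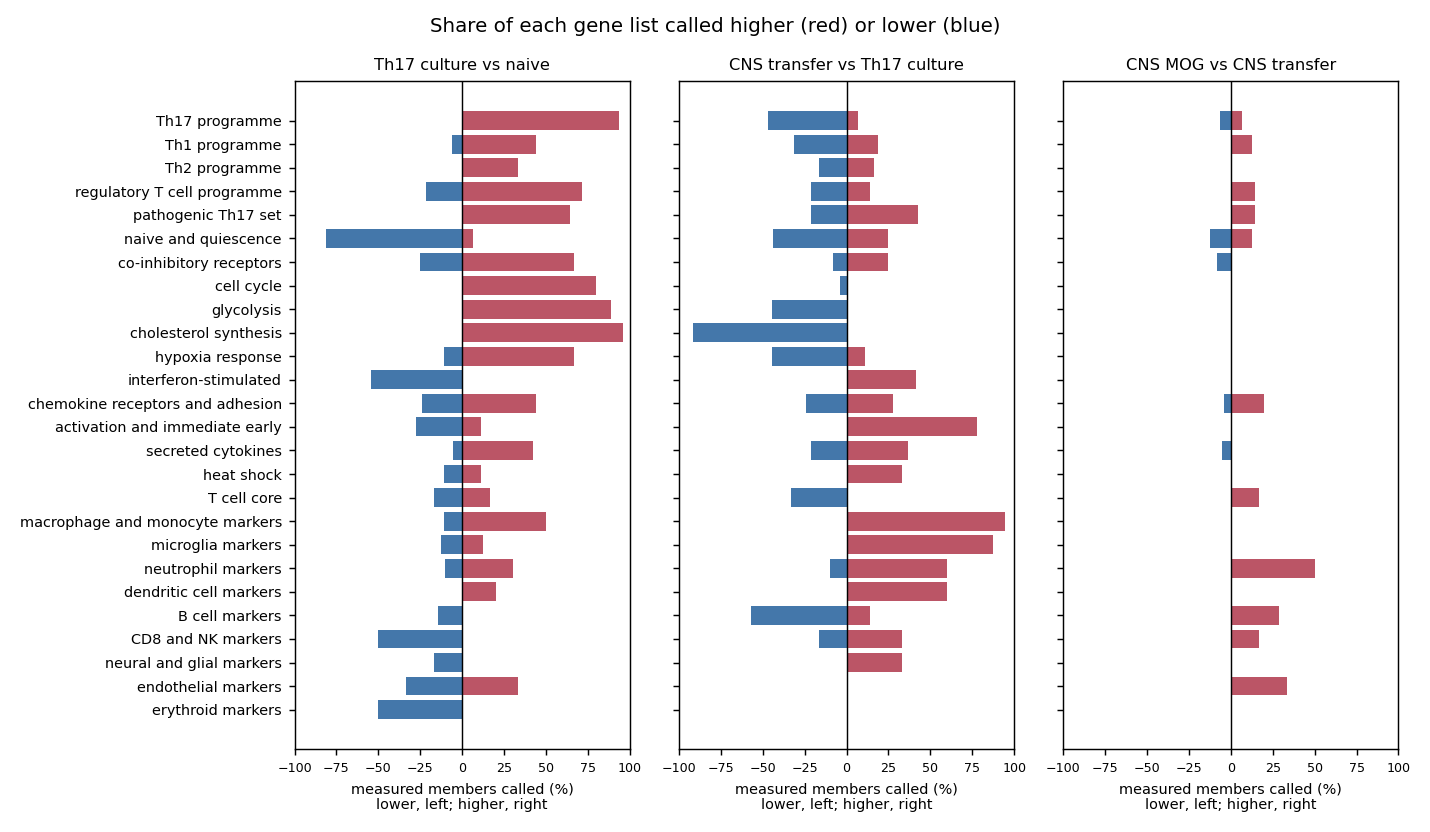
Percent of the measured members of each of 26 gene lists that were called higher (right, red) or lower (left, blue) in the first 3 comparisons. In cultured Th17 cells 22 of 23 cholesterol synthesis genes were higher than in naive cells, and in transferred cells 21 of 23 were lower than in culture.

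The third comparison set CD4+ T cells from the CNS of immunised mice against transferred Th17 cells from the same organ. Foxp3 was 4.25 ± 0.51 log2 higher in the immunised group (limma adjusted p = 0.00196), at 1.75 ± 0.38 against −2.50 ± 1.13 (SD, n = 3 each). Cd177, a surface gene of neutrophils, was 4.15 ± 0.58 higher and Ly6d, a gene of the Ly6 family, 5.18 ± 0.34. Ccl24, an eosinophil-attracting chemokine gene, differed by −9.13 ± 1.23 (adjusted p = 0.00314), at −4.35 ± 0.40 against 4.78 ± 1.87 (SD, n = 3 each), and the macrophage mannose receptor gene Mrc1 differed by −4.57. The cytokine gene Il21 fell by 4.27 ± 0.47 (adjusted p = 0.00109). The Foxp3 probe lies on mm9 chromosome X from 7172301 to 7172360, and the Ccl24 probe on chromosome 5 from 136046667 to 136046726.

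Between the CNS groups Il17a, Il17f, Ifng, Tbx21 and Csf2 did not pass the test. Il17a differed by 1.68 ± 0.80 (adjusted p = 0.274), Il17f by 1.25 ± 0.79 (adjusted p = 0.409), Ifng by 1.36 ± 1.60 (adjusted p = 0.678), Tbx21 by 0.21 ± 0.64 (adjusted p = 0.894) and Csf2 by 0.49 ± 0.68 (adjusted p = 0.739). Il22 was 4.63 ± 1.14 higher in the immunised group (adjusted p = 0.0572) and was called without culture replicate 2 (adjusted p = 0.0114) or 3 (adjusted p = 0.00166), with adjusted p from 0.000132 to 0.179 over all alternatives. The Th17 programme list had 1 gene higher and 1 lower of 15 (3 adjusted over the list alone; median 1.04; camera adjusted p = 0.0904). Only 1 gene was called on leaving out any of the 6 CNS arrays. The list median was 0.63 without transfer replicate 3 and 0.62 without immunised replicate 2, and camera called the list without transfer replicate 2 (1.41, adjusted p = 0.0373) or immunised replicate 3 (1.52, adjusted p = 0.0174).

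Of 10 neutrophil markers 5 rose (8 adjusted over the list alone; median 4.05, and 2.15, 3.77 and 6.91 within slides), at adjusted p = 4.58e-06 with camera and adjusted p = 0.222 with an estimated correlation. None was called without transfer replicate 2 or without immunised replicate 1, 2 or 3, 3 were called without naive replicate 1, 2 or 3, and 2 without culture replicate 1, and 0 with only the 6 CNS arrays in the fit. Camp, an antimicrobial peptide gene, was 5.58 ± 1.09 higher (adjusted p = 0.023). Without transfer replicate 2 or immunised replicate 1, 2 or 3 its adjusted p was 0.0681, 0.0958, 0.0708 and 0.061. Ltf, encoding the granule protein lactoferrin, was 84.4-fold higher at a limma adjusted p of 0.0133, which became 0.0625 and 0.0517 without immunised replicates 1 and 2. That fold rests on transfer arrays that spread widely, with Ltf at 1.10, −1.51 and −4.98 on replicates 1, 2 and 3. Chemokine receptor and adhesion genes had 5 higher and 1 lower of 25 (9 and 2 adjusted over the list alone; median 0.87, and 0.77 to 0.93 within slides; adjusted p = 6.47e-06 with camera and adjusted p = 0.211 with an estimated correlation). The count was 11 without culture replicate 3, 2 without transfer replicate 2, and 1 without transfer replicate 3 or immunised replicate 1 or 2. Of 14 regulatory T cell genes 2 rose, Foxp3 among them (4 adjusted over the list alone; median 0.61, and 0.46 to 1.12 within slides; adjusted p = 0.00388 with camera and adjusted p = 0.206 with an estimated correlation), and 1 was called without naive replicate 1 or 2, transfer replicate 2 or immunised replicate 1, 2 or 3. Of 3 endothelial markers 1 rose, Cdh5, at least 2.22-fold (camera adjusted p = 0.108).

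Macrophage and microglia markers stood at like levels in both CNS groups. With limma 0 of 18 macrophage and 0 of 8 microglia genes were called, and 0 and 0 had an unadjusted p under 0.05. The list medians were 0.13 (−0.87 to 0.61 within slides; camera adjusted p = 0.486) and −0.02 (−0.36 to 0.20 within slides; camera adjusted p = 0.765). Of 25 cell cycle, 24 interferon-stimulated and 23 cholesterol synthesis genes 0 were called by limma, with 2, 4 and 1 at an unadjusted p under 0.05, and 1 of each was called without culture replicate 3, as was 1 cell cycle gene without culture replicate 1. Camera placed these lists at medians of −0.49, 0.65 and 0.17, with adjusted p = 0.000914, 0.00427 and 0.031, against an adjusted p = 0.561, 0.613 and 0.635 with an estimated correlation. The cholesterol median was 0.33, 0.3, 0.29 and 0.31 without transfer replicate 2 or 3 or immunised replicate 1 or 2. Camera also placed the Th1 list (median 0.97, and 0.56 without transfer replicate 3; adjusted p = 0.00035), the pathogenic Th17 set (0.64; adjusted p = 0.0258), the T cell core (0.20; adjusted p = 0.0188) and B cell markers (0.97; adjusted p = 0.011) higher in the immunised group. With an estimated correlation these had an adjusted p = 0.256, 0.521, 0.576 and 0.459.

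Other large rises, from background, were Tmprss13 at least 17.9-fold and Ceacam10 at least 12.2-fold. Other falls included Rnase2a at −5.37, Ear10 at −4.65, Ear2 at −4.64 and Atp6v0d2 at −4.74. Stra6 fell by 5.84 (adjusted p = 0.0126; 3.28e-05 to 0.0615 over all alternatives), a call lost without transfer replicate 3 or immunised replicate 1 or 2. Also, Cth and Gja1 fell to background by at least 12.1-fold and 8.05-fold. The limma test called 600 genes, 344 higher and 256 lower in the immunised group, of which 284 and 199 changed at least 2-fold. The balance turned without transfer replicate 1 (318 higher, 350 lower) and with array weights (2672 higher, 3121 lower). With slide as a block 557 were called. The count was 5793 with array weights, 1256 without culture replicate 3, 356 and 302 without transfer replicates 2 and 3, and 202, 225 and 373 without immunised replicates 1, 2 and 3. The groups also differ in mouse strain, in the receptor transgene and in the signal of sex-linked genes. Transfer recipients lacked Rag1, so they had no mature T or B cells of their own, and were given cultured Th17 cells. Higher Foxp3 and B cell markers in the immunised group cannot be told apart from that difference.

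**Figure D3:**
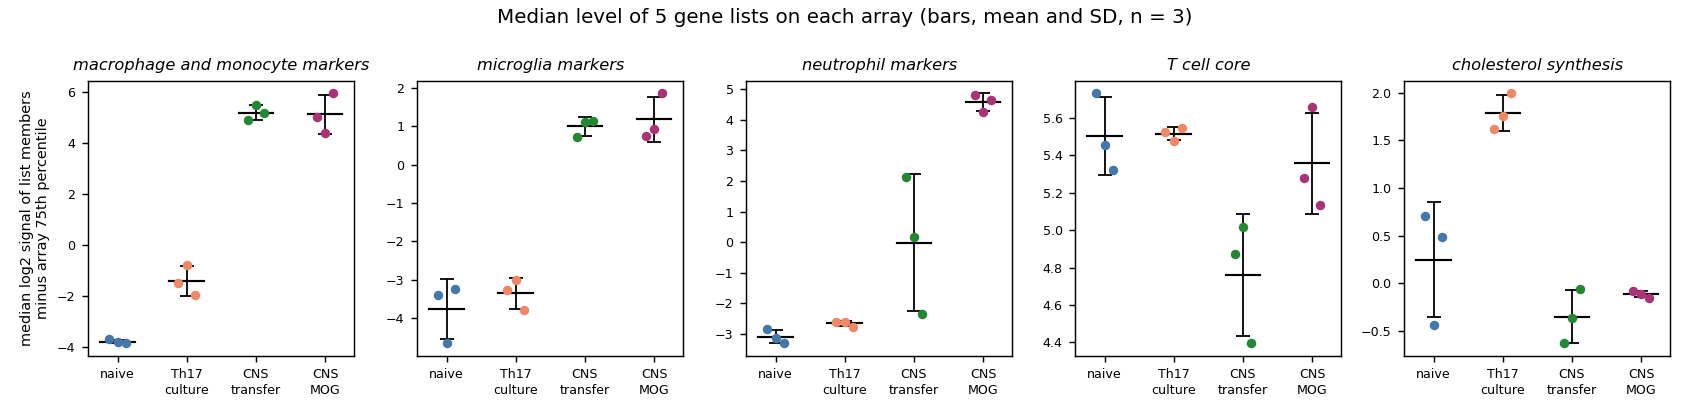
Median log2 signal of the members of 5 gene lists on each of the 12 arrays, relative to the array's 75th percentile, by group, with bars for mean and SD (n = 3). Macrophage and microglia medians were high in both CNS groups, and neutrophil medians spread widely over the 3 arrays of transferred cells.

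Against naive cells, 11 of 15 Th17 programme genes were higher in transferred cells and 0 lower (11 adjusted over the list alone; median 2.64, and 2.34 to 2.96 within slides; adjusted p = 5.76e-05 with camera and adjusted p = 0.256 with an estimated correlation). Il22 and Il23r were not called (−0.79 and 0.45; adjusted p = 0.601 and 0.785). On the same arrays 17 of 18 macrophage genes were higher and 1 lower (18 adjusted over the list alone; median 8.18, or 8.13 at the bounds; adjusted p = 5.25e-14 with camera and adjusted p = 0.159 with an estimated correlation). Of 8 microglia genes 7 were higher (7 adjusted over the list alone; median 4.60, or 3.72 at the bounds; adjusted p = 0.000143 with camera and adjusted p = 0.206 with an estimated correlation). Neutrophil markers had 7 higher and 1 lower of 10 (8 adjusted over the list alone; median 4.06, or 3.53 at the bounds, and 1.22 to 6.23 within slides; adjusted p = 0.0191 with camera and adjusted p = 0.488 with an estimated correlation). Of 12 T cell core genes 7 were lower, and 4 without naive replicate 1 or transfer replicate 3 (7 adjusted over the list alone; median −0.84; camera adjusted p = 0.0658). Csf2 was at least 133-fold higher and Tbx21 2.90 higher. Among genes measured on all 6 arrays, the largest rises were Chil3 at 11.87, Tgfbi at 11.80 and Ccl9 at 9.81. The largest falls among these genes were Dntt, the terminal transferase gene of developing lymphocytes, at −8.00, Dtx1 at −7.03 and Vipr1 at −6.04. In the immunised group Il17a was at least 501-fold and Il17f 3.94 ± 0.79 higher than in naive cells, Csf2 at least 186-fold and Foxp3 2.82 ± 0.51. Among genes measured on all 6 arrays of the immunised group and naive cells, Tgfbi at 11.73, Chil3 at 10.41 and the neutrophil gene S100a8 at 10.07 led the rises. Dapl1 at −6.74, Slc16a5 at −6.56 and Trav14n-1 at −5.26 led the falls. Against cultured Th17 cells the immunised group had higher Apoe (9.90), Camp (9.64) and C1qb (8.89) and lower Enpp2 (−6.30) and Muc13 (−5.61). In limma, 8889 genes were called for transferred against naive cells (3945 higher, 4944 lower), 9007 for immunised against naive (3840 higher, 5167 lower) and 5861 for immunised against culture (2550 higher, 3311 lower). Of these, 3107 higher and 2990 lower, 3014 and 3027, and 1993 and 1959 changed at least 2-fold, so the excess of lower genes lay almost wholly in smaller changes. With slide as a block the counts were 8666, 8868 and 5603.

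Genes called in the same direction in both CNS groups against both naive and cultured cells numbered 1909, of which 1154 were higher and 755 lower in the CNS (1823 with slide as a block). Among genes measured on all 12 arrays, ranked by the smallest of their 4 fold changes, the rises were led by C1qb at 8.81, Apoe at 8.62, Chil3 at 8.11 and the macrophage gene Mpeg1 at 7.08. From background, C1qc rose at least 1541-fold, Ccl7 310-fold and the phagocytic receptor gene Mertk 88.1-fold. The falls were smaller, with the tubulin gene Tubb2b at −2.41, Klhl42 at −2.28 and Ldhd at −2.11.

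These comparisons share control arrays. Fold changes of both CNS groups against naive cells correlated across genes at 0.913 (0.501 in simulated groups with no change), with a covariance of 3.19 against a simulated 0.0755. The shared calls were 3088 higher and 3862 lower, where independent lists would share 813 and 1371. Against cultured cells the correlation was 0.853 (simulated 0.502) and the covariance 1.75 (simulated 0.0759), with 1699 and 1995 shared calls against 326 and 512. Over 20 simulations 0 shared calls were made, but no simulated gene was changed, so few or no calls were bound to follow. The simulations also held no genes particular to the shared naive or cultured group. They therefore cannot gauge how many of the shared calls, or how much of the correlation, the shared controls produce in the real data. Controls of 3 arrays could not be divided into parts of at least 2, so part of the excess may come from the shared controls.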

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

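The counts over other splits were planned, and all other tests in this part were chosen only after the result was seen. 2 sets of genes and 1 gene were picked out because the CNS groups moved in opposite directions from naive cells and the difference between them passed the limma test.

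Lower than naive in transferred cells and higher in immunised mice were 32 genes, 17 of them T cell receptor genes. The other way went 7 genes, 0 of them T cell receptor genes. The CNS groups also differ in the receptor transgene, which for the receptor genes cannot be told apart from a difference in disease. They differ in Rag1 of the host too, which for Foxp3 cannot be told apart either. Foxp3 was 1 of the 32, at 4.248 log2 between the CNS groups. Its fall against naive cells (−1.43, adjusted p = 0.041; 0.00724 to 0.202 over all alternatives) was lost without naive replicate 1 (0.084) or 3 (0.133), culture replicate 1 (0.0542), transfer replicate 1 (0.142) or 2 (0.0838), or immunised replicate 1 (0.0541) or 3 (0.0538). Groups of 3 were not tested for samples far from the others.

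For each of the 6 pairs of groups, 1 of 10 splits of the 6 arrays, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 7463, 5267, 600, 8889, 9007 and 5861, and the highest of the other splits was 0 each time. For both CNS groups against both others, 1 of 100 groupings of the arrays, the real one, gave as many as 1909 genes. The highest other was 0. Other groupings mix arrays of unlike groups, so they test only whether no group differs at all. They cannot test the sharing of genes by both CNS groups.

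The first pattern is the higher macrophage and microglia genes in both CNS groups. Scaling between arrays is excluded, since the macrophage list median was at least 5.056 over 6 scalings and 4 contrasts. RNA of host cells in the CNS isolates may be a source: 2 of 3 transfer arrays carried Xist on both probes together with the Y-linked Ddx3y and Eif2s3y, as 0 of the cultured or naive arrays did, with Xist at 49.6% and 55.8% of the immunised mean, while Apoe and C1qa, abundant in such cells, stood at 8.11 to 8.50 and 4.95 to 5.65 on the transfer arrays. On transfer replicate 1 Xist was not well above background while Apoe stood at 8.11, and the sex of donors and recipients is not in the labels. Expression by the T cells themselves cannot be told apart from this, since 13 of 18 macrophage list members were well above background on all cultured arrays. That test did not cover the microglia list. C1qa, C1qc and Spi1, and the microglia genes P2ry12 and Sall1, were well above background on 0 of 3 cultured arrays. For these 5 genes culture gave no sign of expression by T cells. A sort on CD4 would remove most host cells of this kind, but the labels name none.

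The second pattern is the lower Th17 genes in transferred cells than in culture. Dilution of T cell RNA by RNA of other cells is excluded as the whole cause for 5 of the 15 list members, Il17f, Il22, Il23r and Il1r1 among them, which lay below the lowest T cell core gene (−1.181; core median −0.6518) by more than 2 SE of the difference. The other 10, Il17a and Batf included, had a median of −0.5163 and values of both signs, with Ahr higher at 1.26 ± 0.27 (SE). For those of the 10 that were lower, dilution cannot be told apart from lower expression. The median of all 15 was −1.411. The culture that stood apart, replicate 3, is excluded as the cause, because without it 7 of 7 falling genes were still called lower and 6 of the falls were larger. That these cells express less of the Th17 programme in the CNS, or that a subset with less survived, may account for it as a hypothesis, and neither was tested.

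The third pattern is the higher neutrophil genes in immunised mice than in transfer recipients. Scaling between arrays is excluded (lowest list median 4.029 over 6 scalings). In the immunised isolates the macrophage list median was 0.1263 higher, against 4.052 for neutrophil genes. This excludes a lower share of T cells only where all other cells rose alike. A lower share with neutrophils alone in their place would leave macrophage genes level, so that form was not tested. T cell core medians were not lower, at 5.28, 5.66 and 5.14 on the immunised arrays against 4.87, 5.02 and 4.40 on the transfer arrays. The 3 T cell receptor constant genes went the other way, lower in immunised mice with a median of −1.87, so these values do not settle it. Differing amounts of neutrophil RNA between isolates cannot be told apart from a difference between the models: 7 of 10 list members ordered the 3 transfer arrays alike, fewer than the 8 that explanation asked for and not under the 5 that would have excluded it. S100a8 stood at 5.46, 3.44 and 0.81 on those arrays. A difference in disease between immunised and transfer-induced EAE stays open, as untested.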

How the results depend on the processing

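All alternatives here were planned. Over all named genes, 9942 values were the same, 510 weaker, 12 stronger and 3 reversed. Of list counts 538 moved and 3824 did not, and of list medians 195 moved, 1 reversed and 4166 did not. For genes named by rank of fold change (84 results), 2251 of 2309 values kept direction and call, 58 were weaker and 0 reversed; the weaker ones fell in 11 results, 7 of them on leaving out an array. For list tests by fry or by camera with an estimated correlation, 209 were the same as with the preset correlation, 88 weaker and 15 stronger. Signal over background limits what lies under log2 −5.95 to −5.17. Leaving out genes with saturated spots was not run, since 0 spots were saturated.

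The counts are in the order Th17 against naive, transfer against Th17, immunised against transfer, transfer against naive, immunised against naive, immunised against Th17, and shared; the main values are 7463, 5267, 600, 8889, 9007, 5861 and 1909. Fewer genes passed the stricter thresholds by their construction: at an adjusted p under 0.01, 4709, 2687 and 185 for the first 3, 3278 for immunised against Th17 and 1018 shared; with treat at 1.5-fold 3377, 1937, 168, 4476, 4355, 2334 and 826. Array weights gave more, 7933, 5793, 10306 and 3269 for transfer against Th17, immunised against transfer, immunised against Th17 and shared. Immunised against transfer gave 371 with no filter and 367 with genes well above background on all 12 arrays, and transfer against Th17 gave 3313 with only the 6 arrays compared. For these the cause was not tested. Leaving out 1 array gave 5891 to 7394, 3663 to 5345, 202 (without immunised replicate 1) to 1256 (without culture replicate 3), 7508 to 9928, 6783 to 10328, 4131 to 5820 and 1421 to 2004.

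The neural and glial list median for transfer against Th17 was −0.1792 with genes well above background on all 12 arrays, and Kdr for Th17 against naive was −0.03133 with the mean of kept probes per gene, both reversed; the cause was not tested. Ifng for Th17 against naive, which was not called, reversed to −0.09351 and −1.515 without culture replicates 1 and 2 and was 2.725 without replicate 3. With median scaling the median of all genes moved from −0.0772 to 0.0322 for Th17 against naive and from −0.098 to −0.212 for transfer against Th17. For Th17 against naive the higher share of calls was 49.2%, 55.99% with median scaling and 42.6% with normexp and quantile. For transfer against Th17 it was 45.28%, and 51.99% with the 75th percentile of probes above background on all arrays. The higher share of calls for immunised against transfer was 57.33%, and 46.12% with array weights. For transfer against naive it was 44.38%, and 37.01% with normexp and quantile; for immunised against naive 42.63%, and 35.89%. With treat at 1.5-fold, which favours large changes, the 6 higher shares were 60.91%, 59.53%, 64.29%, 55.99%, 55.38% and 60.03%.

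Taken over all genes, replicate numbers did not pair the arrays. Deviations of 18 same-number pairs correlated at −0.198 to 0.204 (median 0.0359, 4 over 0.1), and 5 of 12 arrays were closest to their own number. This does not exclude pairing for smaller sets of genes. Th2 list medians on replicates 1, 2 and 3 were −0.76, −3.74 and 2.20 in culture. In transferred cells they were 1.10, −0.39 and 2.53, in the same order. Pairing of single genes or lists was not tested. With a fixed replicate block the counts were 7167, 5069, 557, 8666, 8868, 5603 and 1823, and with a random block 7447, 5246, 596, 8870, 8977, 5835 and 1898.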

Other observations

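The groups of genes in this part and the tests on them were all chosen after values were seen. T cell receptor variable genes differed between the CNS groups. These groups also differ in the receptor transgene, and the 2 differences cannot be told apart. Of 20 beta variable genes 17 were higher in immunised mice than in transferred cells by limma, against 344 of all 18630 genes. The median was 5.97, or 4.76 at the bounds, and 15 to 18 were higher on leaving out 1 array. V15, V20 and V19 were at least 80.0-fold, 68.5-fold and 58.9-fold higher. In naive cells, transgenic and without EAE, these genes stood at −4.28, −3.80 and −3.66, against 0.71, 0.62 and 0.27 in immunised mice. For them the gap was thus there without transfer EAE. V13-1 was closer, at 0.14 in naive cells against 0.50. No cells without both the transgene and EAE were measured. Of the 20, 15 were not well above background on all 3 transfer arrays and were kept through other groups. The filter thus favoured such a count. Of 30 alpha variable genes 16 were higher and 2 lower, the lower being 9N-4 at −5.12 and 9D-1 at −4.33. In naive, cultured and transferred cells, all from transgenic mice, 9N-4 stood at 4.8, 4.6 and 4.0, against −1.1 in immunised mice. The levels of 9D-1 were 3.8, 3.5 and 2.9, against −1.5. The 3 constant genes were lower in immunised mice than in transferred cells, with a median of −1.87. Immunoglobulin variable genes were lower in transferred cells than in naive cells, 52 of 52, with a median of −6.06, or −4.145 at the bounds. They were already lower in culture, 49 of 52, with a median of −3.83 at the bounds. Of the 52, 48 were not well above background on all 3 transfer arrays, so the filter kept them only through other groups. That filter favours lower values in transferred cells, and the count is not a test.

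No list of alternatively activated macrophage genes was fixed, and of the fixed macrophage list 0 of 18 genes were called between the CNS groups (limma; 0 at an unadjusted p under 0.05). Single genes of that kind stood higher on the 3 transfer arrays than on the 3 immunised arrays: Retnla at 0.01, −3.22 and 4.58 against −7.44, −7.51 and −7.18, Ccl24 at 4.30, 3.19 and 6.85 against −3.90, −4.57 and −4.60, and Mrc1 at 3.59, 4.14 and 5.94 against 0.01, −0.70 and 0.64. The Retnla call (adjusted p = 0.0184; 0.00249 to 0.084 over all alternatives) was lost without immunised replicate 1, 2 or 3, and Arg1 and Chil3 were not called (adjusted p = 0.343 and 0.552). The type 2 cytokine gene Il4 stood at 2.40, −0.25 and 3.54 on the transfer arrays and at −2.57, −2.16 and −4.34 on the immunised arrays. Il13 stood at 0.49, −0.84 and 3.92 against −3.11, −3.44 and −2.44. Neither passed the limma test between these groups (adjusted p = 0.205 and 0.2), nor did any of the 6 Th2 list genes, 3 of them with an unadjusted p under 0.05. In culture, replicate 3 had Il4 at 2.88 against −1.46 and −7.09.

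Sex-linked genes divided the arrays otherwise than the groups do. Xist was well above background on both probes on naive replicates 2 and 3, the 3 immunised arrays and transfer replicates 2 and 3. The Y-linked Ddx3y and Eif2s3y were well above background on naive replicate 1, the 3 cultured arrays and the 3 transfer arrays. On cultured replicates 1 and 2, Xist reached 3.92% and 5.18% of the immunised mean on 1 probe.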
